A study of Rattus norvegicus with 6 samples.

How the data were processed

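Kidney RNA was measured on 6 Affymetrix 1-colour arrays, 3 from Dahl salt-sensitive (S) rats and 3 from congenic rats. The labels describe the animals as adult males and give each array its own animal number, so each array was treated as 1 rat. Total RNA was extracted with TRIzol, cleaned on RNeasy columns and converted to biotin-labelled cRNA, per the labels' protocols.

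The deposited values are probe set intensities on a linear scale, computed with GCOS 1.4 per the submitters' processing notes. The settings of that software, its detection calls and the array annotation build are not given in the sources used here. The deposited intensities ran from 0.12 to 60077, and the mean of each array after trimming 2% of probe sets at either end was 500.2, so the arrays had been brought to 1 common level before deposit. No further normalisation was applied in the analysis reported here. Such scaling equalises the trimmed mean of the arrays and leaves any difference that varies with signal strength in place.

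Of 31099 probe sets, 57 were array controls and were left out, which left 31042. Values under the 10th percentile of the whole table, a signal of 12.3, were raised to it, and log2 was taken. The 15521 probe sets whose mean log2 signal lay above the median of all 31042 were tested, and they covered 9334 named genes. The number of arrays limits the precision: the median standard error of a log2 difference was 0.14. Without detection calls, low signals could not be separated from background probe set by probe set.

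Probe sets were named from the array annotation, with symbols updated through Entrez identifiers in the gene table of assembly GRCr8. Exactly 1 symbol was found for 20826 probe sets, several for 436 and none for 9780. Of the named probe sets, 20758 matched through an Entrez identifier and 68 kept the platform's symbol. Probe sets with several symbols were not named. GRCr8 was used for names and gene order alone, because no build is named for the array, and so no coordinates are given.

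The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, prior degrees of freedom 10.7), congenic minus S, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of adjusted p 0.05. A descriptive second count used unadjusted p below 0.01 with a fold of at least 1.5. A single gene was also compared by the 2-sided exact permutation test, which with 3 against 3 cannot go below p = 0.1. Groups share no replicate numbers in the labels, so no pairing was used.

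In all, 27 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of their entries, 869 matched a current symbol, 4 an older symbol and 2 none. Each gene was represented by its tested probe set of highest mean signal. The 25 lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the lists. Each list was tested again with an estimated correlation and with fry, whose directional p tests whether genes move on balance one way and whose mixed p tests for change in either direction. The 25 tested genes on either side of Adamts16 in gene order were compared with all other tested genes by a 2-sided Fisher's exact test.

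The genes named are Adamts16, then all genes past the adjusted threshold. Because fewer than 24 passed, the list was filled to 12 genes per direction with those of smallest unadjusted p whose 3 congenic values lay all above or all below the 3 S values with a fold of at least 1.5. From each list up to 3 genes of smallest p are named where none passed, and from the neighbours of Adamts16 up to 6 with unadjusted p below 0.05.

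The procedure was tested on simulated data: 10 simulations of 15521 probe sets with the means and spreads of these arrays, each with 200 probe sets changed by known folds. At adjusted p 0.05 it recovered 43% of 1.5-fold, 87% of 2-fold, 98.6% of 3-fold and 100% of 4-fold changes, and 5.95% of its calls were false. The simulated probe sets were drawn independently of each other, and strong changes planted together ease the adjusted threshold. These shares therefore need not hold for the real arrays, and they do not show that changes of such folds were absent. Alternatives covered the floor, the pseudocount (16), the filter on low signals, the normalisation between arrays, the variance model, array weights, a block for the number that opens each array title, the choice of probe set, the number of neighbours and each array left out in turn. Cyclic loess normalisation was added after the data were seen. Figures were drawn with matplotlib 3.10.9.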

Results

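Gene expression was profiled in kidneys of 2 rat strains. The S strain is the inbred Dahl salt-sensitive rat, which develops high blood pressure. The congenic strain carries a chromosome 1 segment of the Lewis rat on the S background. By its title, the series was part of positional work on variants of Adamts16, a secreted metalloprotease gene, in inherited hypertension. Each strain contributed 3 rats with 1 array each, and values are mean scaled signal ± SD over 3 rats. Median signals of the 6 arrays lay between 163 and 178. Across probe sets, which are not independent replicates, Spearman correlations were 0.967 to 0.973 between arrays of 1 strain and 0.960 to 0.973 between strains. The 3' to 5' signal ratio of beta-actin, a sign of RNA integrity, was 2.13 ± 0.156 in S and 2.01 ± 0.0594 in congenic kidneys. The corresponding ratios of GAPDH were 1.15 ± 0.0356 and 1.16 ± 0.0371, and the ratios of all 3 control genes measured overlapped between strains.

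The first question was whether Adamts16 itself was expressed at another level in the congenic kidney. Its single probe set read 121 ± 27.5 in S and 130 ± 91.4 in congenic kidneys, below the median signal of 172. The S rats gave 147, 92.4 and 125, and the congenic rats gave 43.5, 121 and 226. Because the probe set lay under the filter on low signals, its difference was taken from a fit of all 31042 probe sets. The log2 difference was -0.17 with a standard error of 0.64 and a 95% interval of -1.76 to 1.42, so that no difference was detectable at this precision. The exact permutation test gave p = 0.8. The sign rested on congenic replicate 1, without which the log2 difference was 0.47, and with a block for the title number it was 0.02. Ice1, a subunit gene of the little elongation complex and a neighbour of Adamts16, read 359 ± 11.3 in S and 353 ± 39.9 in congenic kidneys.

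**Figure D1:**
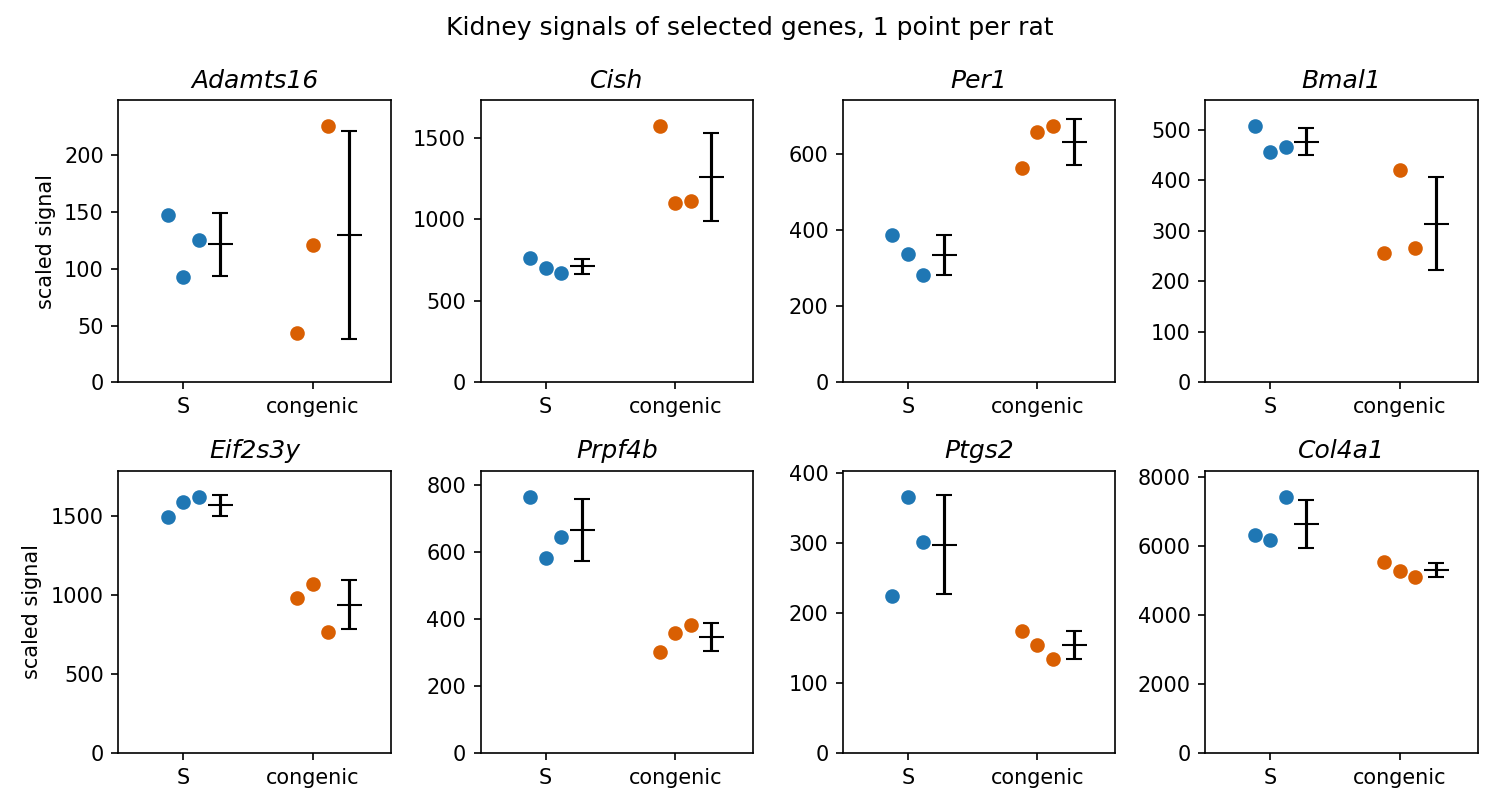
Scaled array signal (linear axis from 0) of 8 genes in S (blue) and congenic (orange) kidneys, with 1 point per rat and the mean ± SD beside each group. Adamts16 overlapped between strains, from 43.5 to 226 in congenic rats, whereas the Per1 signals of 564 to 674 in congenic rats lay above the 282 to 388 of S rats.

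The second question was which other transcripts differed between the strains. Among the genes with higher congenic signals, Cish, an inhibitor of cytokine signalling induced by STAT5, read 712 ± 48.2 in S and 1262 ± 269 in congenic kidneys, a fold of 1.75. Per1, a core repressor of the circadian clock, read 336 ± 52.8 and 632 ± 59.3, a fold of 1.89. Among those with lower congenic signals, Eif2s3y, the Y-linked copy of a translation initiation factor subunit, read 1566 ± 65.5 and 935 ± 155. Prpf4b, a kinase of pre-mRNA splicing, read 664 ± 92.8 and 347 ± 41.0, a log2 difference of -0.94, while its 2 other tested probe sets had -0.29 and -0.09. In limma these 4 genes, and also Tcim and Nfia, had adjusted p = 0.0697, the smallest value obtained, and so they did not pass the threshold of 0.05.

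The other genes named as higher in each congenic rat than in each S rat also failed the adjusted threshold. Tcim and Nfia, the latter a nuclear factor I transcription factor, each had a log2 difference of 0.60. The glutamine transporter gene Slc38a3 had 0.67, and Smarca4, the ATPase of a SWI/SNF chromatin remodelling complex, had 0.68. Stat5b, which carries growth hormone signals to the nucleus, read 150 ± 41.9 in S and 279 ± 41.8 in congenic kidneys, a log2 difference of 0.92. The endothelial transcription factor gene Klf2 had 0.77 and Arid5b had 0.82. The remaining 3 were Ankrd37 (0.72), Kctd15 (0.61) and Naxd (0.61), the last a repair enzyme for damaged NADPH. A second probe set of Cish had a log2 difference of 0.74, whereas the 3 other Klf2 probe sets had 0.12, -0.06 and -0.07, the 2 others of Nfia 0.18 and -0.17, and the 2 others of Smarca4 0.04 and -0.09.

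Ccdc141 had the lowest log2 difference of the named genes, -1.35 with a standard error of 0.27, from 376 ± 89.9 in S to 151 ± 58.1 in congenic kidneys. Further genes with lower congenic signals were Ankrd13c (-0.84), Tut4 (-0.85), a terminal uridylyltransferase gene, and Tmem38a (-0.82), an intracellular cation channel gene. Fndc3a had -0.81, Fam43a -0.76 and Pdcd4, a translation inhibitor gene, -0.73. The ion channel and kinase gene Trpm7 and Zfp91 each had -0.64. Vnn1, which encodes the pantetheinase vanin 1, read 1324 ± 186 in S and 857 ± 69.3 in congenic kidneys. The other tested probe set of Trpm7 had 0.09, and those of Zfp91 had -0.27, 0.13, 0.02, -0.02 and 0.01. The others of Ankrd13c had -0.40, 0.13 and -0.31, that of Tmem38a -0.39, and those of Pdcd4 -0.26, -0.05 and -0.04. Of the 24 named genes, 11 had further tested probe sets, and 15 of those 24 further probe sets had the sign of the one named.

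Over the 15521 probe sets tested, limma called 0 at adjusted p 0.05, while 12 passed at 0.1, of which 7 were higher and 5 lower. At unadjusted p below 0.05 there were 1602 (732 higher and 870 lower), against 776 by chance, and at p below 0.01 there were 475, against 155. Probe sets are correlated, and other splits of the 6 arrays into 3 against 3 gave 386 to 1139 at p below 0.05. Some of these other splits therefore exceeded 776. Each of them has 2 rats of 1 strain and 1 of the other on either side, so part of a strain difference could remain in it. The 3 congenic values lay all above or all below the 3 S values for 15.97% of probe sets, where chance gives 10%. With a fold of at least 1.5 as well as p below 0.01, 123 remained, 36 higher and 87 lower, a share of 29.3% higher. That share was 44.3% after quantile normalisation (47 higher and 59 lower), 41.4% with arrays centred on the median (48 and 68) and 45.3% after cyclic loess (48 and 58). With 1 array left out it ran from 19.0% without congenic replicate 1 (32 and 136) to 44.1% without S replicate 3 (45 and 57). The count at adjusted p 0.05 was 10 with centring, 41 without S replicate 1, 6 without congenic replicate 1 and 3 without congenic replicate 3, and the count of 123 was 189 without S replicate 1. The count of 12 at adjusted p 0.1 was 103 without S replicate 1, 35 without congenic replicate 1, 7 without congenic replicate 3, 2 without congenic replicate 2, and 0 without S replicate 2 and without S replicate 3. It was 23 with array weights and 0 with a block for the title number, without the variance trend or without the filter on low signals.

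Grouped by function, 8 of the 25 tested lists passed camera's adjusted threshold at the preset correlation. Higher in congenic kidneys were proximal tubule markers, xenobiotic and steroid metabolism, immune cell markers, oxidative phosphorylation and the chromosome 1 neighbourhood of Adamts16. Lower were the extracellular matrix, loop of Henle and distal tubule markers, and the ADAMTS family. No list passed with an estimated correlation (smallest adjusted p = 0.33) or with fry's directional test (smallest adjusted p = 0.191). Single members of these 8 lists passed in 0 cases over all probe sets tested, and adjusted over the list alone in 1 case, RT1-Bb. After quantile normalisation or cyclic loess, the matrix and loop of Henle lists were the 2 that passed, and of the 8 lists 4 passed without S replicate 1, 2 without S replicate 3, 3 without congenic replicate 1 and 3 without congenic replicate 3. Of the 6 fits with 1 array left out, the proximal tubule list passed in 6, the matrix list in 5, loop of Henle and oxidative phosphorylation in 3 each, the ADAMTS list and the chromosome 1 neighbourhood in 2 each, and xenobiotic and immune genes in 1 each.

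Proximal tubule markers were higher, with 22 of 28 measured genes positive and a median log2 difference of 0.12 (camera adjusted p = 6.08e-04). Their adjusted p was 0.33 with an estimated correlation, and they did not pass after quantile normalisation or cyclic loess. Their mean log2 difference was 0.11 and ran from 0.04 to 0.14 over the alternatives. The sulphate transporter gene Slc13a1 had a log2 difference of 0.30, the hepatocyte nuclear factor gene Hnf4a 0.23 and the aspartic protease gene Napsa 0.21, and 5 genes of the list reached unadjusted p below 0.05. Loop of Henle and distal tubule markers were lower, with 12 of 15 negative and a median of -0.09 (camera adjusted p = 0.0359; adjusted p = 0.33 with an estimated correlation). The list did not pass without S replicate 3, without congenic replicate 1 or without congenic replicate 3. S replicate 3 had a mean log2 deviation of 0.11, against 0.01 in each other S rat. The tight junction genes Cldn8 and Cldn10 had -0.33 and -0.22, whereas Umod, the uromodulin gene of the thick ascending limb, named after its values were seen, had 0.25. Slc12a1, the sodium-potassium-chloride cotransporter blocked by loop diuretics, read 8218 ± 1026 in S and 6847 ± 677 in congenic kidneys. Collecting duct and medulla markers did not pass (adjusted p = 0.512). Among them Hsd11b2, the enzyme that shields the mineralocorticoid receptor from glucocorticoids, had 0.25, Krt7 0.18 and the ammonia transporter gene Rhcg 0.19.

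Extracellular matrix genes were lower, with 27 of 42 negative and a median of -0.07 (camera adjusted p = 0.0268; adjusted p = 0.33 with an estimated correlation). The basement membrane collagen genes Col4a1 and Col4a5 had log2 differences of -0.32 and -0.25, and the matrix protein gene Sparc had -0.48. The mean log2 deviation of the matrix list was 0.11, 9.41e-04 and 0.02 in S replicates 1 to 3. It was 0.00349, -0.06 and -0.07 in congenic replicates 1 to 3, so that the strains overlapped. Without S replicate 1 the matrix list had adjusted p = 0.218. The ADAMTS list, the family of Adamts16, was lower, with 8 of 9 measured members negative (camera adjusted p = 0.0415; adjusted p = 0.33 with an estimated correlation). Of these, 7 are proteases (6 negative) and 2, Adamtsl4 and Adamtsl2, encode ADAMTS-like proteins without a protease domain. The smallest p values were those of Adamts5 at -0.39, Adamts10 at -0.36 and Adamts1 at -0.21. Congenic replicate 1 had the lowest mean log2 deviation of this list, -0.23, against -0.05 and 0.02 in the other congenic rats, and without it the list had adjusted p = 0.291. The ADAMTS list also did not pass with a block for the title number, with array weights or with any 1 S rat left out. Other metalloproteases and their inhibitors did not pass (adjusted p = 0.629). Of these, Adam15 had 0.41, the brush border protease gene Mep1a 0.18 and Mmp24 0.15. Endothelial, smooth muscle and stromal markers missed the threshold (adjusted p = 0.0595), with 17 of 25 negative. Their members went both ways, with Vwf at 0.63, Acta2 at -0.36 and Ehd3 at -0.42.

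Oxidative phosphorylation genes were higher, with 39 of 51 positive and a mean log2 difference of 0.06 (camera adjusted p = 0.0359; adjusted p = 0.723 with an estimated correlation), but this mean was 0.00621 after quantile normalisation and -2.37e-04 after cyclic loess. The mean log2 deviation of the list was -0.05 in congenic replicate 1, within the -0.07 to -0.01 of S rats, and 0.09 and 0.06 in the other congenic rats. The ATP synthase subunit genes Atp5me and Atp5f1e had 0.59 and 0.21, and the complex II gene Sdhc had 0.19. Xenobiotic and steroid metabolism genes were higher, with 17 of 25 positive (camera adjusted p = 0.0359; adjusted p = 0.33 with an estimated correlation). The monooxygenase gene Fmo2 had 0.42, the efflux pump gene Abcc4 0.29, and Por, the electron donor of cytochrome P450 enzymes, 0.25. This list shares 3 genes with the proximal tubule markers, which were higher too, namely Slc22a6 (0.14), Slc22a8 (0.08) and Cyp2e1 (-0.04). Immune cell and inflammation genes were higher, with 18 of 24 positive (camera adjusted p = 0.0415; adjusted p = 0.414 with an estimated correlation). Their mean log2 deviation was 0.11 and 0.10 in congenic replicates 1 and 3, but -0.03 in congenic replicate 2, within the -0.10 to -0.03 of S rats. The class II antigen gene RT1-Bb had 0.35, the NF-kB inhibitor gene Nfkbia 0.36 and the macrophage marker Cd68 0.63. Interferon response genes did not pass (adjusted p = 0.107), although Irf7 (0.45) and Ifi27 (0.27) passed adjusted over the list alone, and Psmb9 had 0.32.

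**Figure D2:**
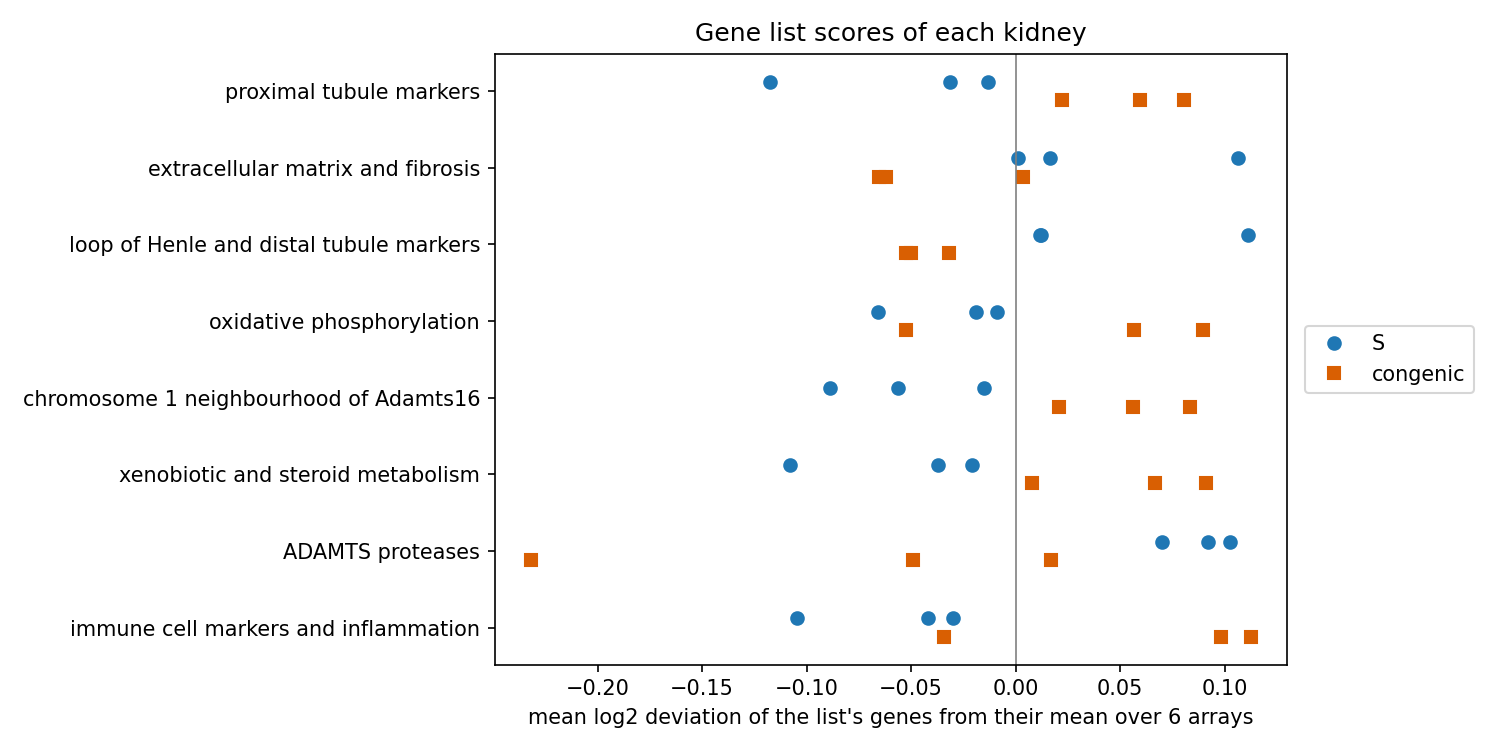
Mean log2 deviation of a list's genes from their mean over 6 arrays (horizontal axis), for the 8 lists past camera's adjusted threshold, with 1 point per S (blue circle) or congenic (orange square) rat. Proximal tubule scores were -0.12 to -0.01 in S and 0.02 to 0.08 in congenic rats, whereas the strains overlapped for the oxidative phosphorylation, matrix and immune lists. The mean difference of oxidative phosphorylation was -2.37e-04 after cyclic loess.

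By fry's mixed test, for change in either direction, 8 lists passed (smallest adjusted p = 0.00406). This test does not compare a list with other genes. Of the 9284 tested genes away from Adamts16, 10.4% reached unadjusted p below 0.05, so passing it does not set a list apart from the rest. Circadian clock genes did not pass camera (adjusted p = 0.091) but passed the mixed test (adjusted p = 0.0275), and Per1 and Bmal1 passed adjusted over the list alone. Bmal1, the activator of the clock, read 477 ± 27.0 in S and 314 ± 92.2 in congenic kidneys, and the repressor gene Nr1d2 read 728 ± 208 and 1272 ± 480. Fatty acid oxidation and PPAR targets also passed the mixed test alone (adjusted p = 0.0148), with Ppard (-0.67) and Hadh (-0.32) past adjusted over the list alone and Acsl1 at -0.28. For arachidonate and eicosanoid metabolism the mixed test gave adjusted p = 0.0148. Ptgs2, the inducible cyclooxygenase, read 297 ± 70.8 in S and 154 ± 19.3 in congenic kidneys and passed adjusted over the list alone. Alox15 had -0.55 and the prostaglandin-degrading enzyme gene Hpgd -0.37. Among oxidative stress and glutathione genes (mixed adjusted p = 0.0275), Gstp1 and Gss had 0.28 and 0.25 and the mitochondrial superoxide dismutase gene Sod2 had -0.36.

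The lists of blood pressure control did not pass camera's threshold. The renin-angiotensin-aldosterone list had adjusted p = 0.75 by camera, with Agtrap at 0.22 and the angiotensin receptor gene Agtr1b at -0.27. Tubular transport genes had adjusted p = 0.629, with the potassium channel gene Kcnj16 at 0.20 and the bicarbonate cotransporter gene Slc4a4 at -0.21. The vascular tone list also had adjusted p = 0.629 and passed the mixed test (adjusted p = 0.0454). In it, the adducin gene Add1 read 6105 ± 306 in S and 7227 ± 112 in congenic kidneys, Npr2 had a log2 difference of -0.44 and Ddah1, which degrades an inhibitor of nitric oxide synthase, had 0.20. Tubular injury genes had adjusted p = 0.576, with Tff3 at 0.34, Cp at -0.26 and Lgals3 at 0.21. Podocyte markers had adjusted p = 0.991, with Tcf21 at -0.26, Cdkn1c at 0.19 and Synpo at 0.14.

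The other lists did not pass either. Immediate-early and heat-shock genes had adjusted p = 0.688, with Gadd45g at 1.08, Ier3 at -0.32 and Dusp1 at -0.35. Cholesterol and lipid synthesis had adjusted p = 0.868, with Insig2 at -0.49, Fdft1 at 0.28 and Msmo1 at 0.27. Cell cycle genes had adjusted p = 0.512, with Ccnd1 at 0.20, Ccnb2 at 0.37 and Top2a at -0.40. Adipocyte markers had adjusted p = 0.629, with Pck1 at 0.21, Aqp7 at 0.14 and Cidec at -0.22. The list median and the direction of camera differed in sign for 4 lists (renin-angiotensin-aldosterone, immediate-early, cholesterol and adipocyte), and for the adipocyte list the mean differed too. Of 3 measured erythrocyte markers, too few to test as a list, Hbb had -0.42, Alas2 -0.55 and Slc4a1 -0.08. The first 2 passed adjusted over these 3 genes alone (limma, adjusted p = 0.0276), but neither passed over all probe sets tested. An adjustment over a list alone does not account for the number of lists. Mrap, the 1 measured adrenal marker, had 0.04.

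The last question was whether genes next to Adamts16 differed, since the congenic rat carries a donor segment of chromosome 1. The extent of that segment is not given here, so how many of these genes lie in donor DNA is not known. The tests below therefore describe neighbours of Adamts16 rather than the segment. The list for this part of chromosome 1 was higher, with 17 of 20 measured genes positive (camera adjusted p = 0.0359; adjusted p = 0.33 with an estimated correlation). Clptm1l read 3241 ± 374 in S and 4035 ± 434 in congenic kidneys, Tent4a had a log2 difference of 0.33, and the amino acid transporter gene Slc6a18, also in the proximal tubule list, had 0.16. The list shares Sdha and Ndufs6 with oxidative phosphorylation. By gene order in GRCr8, 6 of the 50 nearest tested genes (12%) reached unadjusted p below 0.05. Of these 50 genes, 28 had positive differences, and 2 of the 6 were higher. The 6 were Clptm1l, Tent4a, Arid1b (-0.35), Snx9 (-0.26), Tcf21 and Ccdc127 (-0.49). This share could not be distinguished from the 10.4% of the other 9284 genes (Fisher's exact test, p = 0.643). It was 18% among the nearest 100 genes (Fisher's exact test, p = 0.0195) and 10% among the nearest 20 (p = 1). When the brightest 7761 probe sets alone were tested, 12 of the 50 nearest genes with such a probe set reached unadjusted p below 0.05 (Fisher's exact test, p = 0.0287). Those 50 genes were another set, which reached farther from Adamts16. Without congenic replicate 3 the count of 6 was 3.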

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

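Cyclic loess was the 1 alternative chosen after the data were seen. The low number of arrays and the missing measure of signal over background limit what these values can separate, above all for Adamts16, whose signal lay below the median. The congenic means of Ptgs2 (154) and Ccdc141 (151) also lay below that median of 172. So did the S means of Stat5b (150) and Klf2 (164). Where no cause is given for a shift below, the cause was not tested.

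Over 17 alternatives to the fit, the 24 named genes gave 398 values, of which 21, in 16 genes, passed adjusted p 0.05. The count at that threshold was 0 and became 10 with arrays centred on the median, 12 at adjusted p 0.1 and 0 to 41 with 1 array left out (41 without S replicate 1, 6 without congenic replicate 1, 3 without congenic replicate 3). The count of 123 at p 0.01 and 1.5-fold became 269 with no filter, where more probe sets were tested, 33 among the brightest 7761 probe sets, where fewer were, and 102 to 189 with 1 array left out. With the title number as a block it was 145.

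The Adamts16 log2 difference of -0.17 changed sign to 0.025 with the title number as a block, and ranged from -0.72 to 0.47 with 1 array left out (0.47 without congenic replicate 1).

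Of the 8 lists past camera's threshold, 2 passed after quantile normalisation, 2 after cyclic loess, 5 with no filter, 3 among the brightest 7761, 4 without the variance trend, 5 with array weights, 0 with an estimated correlation and 0 with fry's directional test. With 1 array left out, 2 to 6 of the 8 passed (4 without S replicate 1, 2 without S replicate 3, 3 without congenic replicate 1 and 3 without congenic replicate 3), and 2 to 7 of all 25 lists. Lists that passed in some settings alone included the circadian clock, with the title number as a block and without congenic replicate 2. Over the alternatives at the preset correlation, the matrix list passed in 17 of 18, proximal tubule in 16, loop of Henle in 14, oxidative phosphorylation in 11, the chromosome 1 neighbourhood in 10, the ADAMTS list in 9 of 17, xenobiotic metabolism in 7 of 18 and immune genes in 6. For oxidative phosphorylation, camera's direction turned after quantile normalisation, where the mean stayed positive at 0.00621, and the mean turned to -2.37e-04 after cyclic loess. Of 499 list values under alternatives, 35 had a mean of the other sign, 33 of them for lists past the threshold in neither setting. Among other named genes, Slc4a1 became 0.064 and Mrap -0.020 without S replicate 3. With 1 array left out Slc4a1 ranged from -0.21 to 0.064 and Mrap from -0.020 to 0.083.

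Genes next to Adamts16 at unadjusted p below 0.05 numbered 12 among the brightest 7761 probe sets (Fisher's exact p = 0.0287), 2 with 10 genes per side, 18 with 50 per side (p = 0.0195), and 3 to 7 with 1 array left out (3 without congenic replicate 3). Among the brightest probe sets the neighbours were another set of genes, which reached farther from Adamts16.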

Other observations

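The tests of clock phase, of matching on signal, of cortex share, of other probe sets of a gene and of the splits at adjusted p 0.1 were chosen after the results were seen, and the STAT5 and glucocorticoid target lists were written after Cish and Per1 had been seen. Some wording of the clock, matching and probe set tests was also revised after their values were known, and the interval of the blocked clock contrast was added then.

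The clock genes differed in sign by phase, but the contrast between phases had exact permutation p = 0.2 and another split of the arrays gave a larger one. All 10 measured genes that peak with Per1, among them Per3 (log2 difference 0.52), Dbp (0.31), Wee1 (0.26) and Usp2 (0.29), had positive differences, with a mean of 0.38. All 4 measured genes that peak with Bmal1, namely Bmal1, Clock (-0.19), Nfil3 (-0.22) and Cry1 (-0.07), had negative differences, with a mean of -0.28. Cry2, placed in neither set, had -0.30. Congenic replicates 1 and 3 carried most of the contrast, with Nr1d2 signals of 1617 and 1475 against 725 in congenic replicate 2 and 507 to 922 in S rats. Per1 was higher in all 3 congenic rats, at 564, 658 and 674 in replicates 1 to 3, than in S rats, at 282 to 388. Both measured Y-linked genes were negative, Eif2s3y at -0.76 and Uty at -0.34, with unadjusted p = 0.045 for Uty.

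The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split of the 10 with as many calls in each count. It gave 12 probe sets at adjusted p 0.1, against 2 in the highest other split, but that 12 became 0 without S replicate 2, without S replicate 3 and with the title number as a block, and 103 without S replicate 1, 35 without congenic replicate 1, 7 without congenic replicate 3 and 2 without congenic replicate 2. It gave 123 at p 0.01 and 1.5-fold, against 77, and 8 lists, against 5. The split by title number gave 31 probe sets and 2 lists.

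A candidate explanation of the clock pattern is collection at another phase of the daily cycle. The contrast of the 2 phases was 0.66 (exact permutation p = 0.2), and another split reached 0.73. The prediction that the real split would give the largest contrast was therefore not met. The gap to the other split was smaller than the standard error of the contrast, so it does not settle the question. Scores ran from -0.22 to 0.63 in the congenic group. With the title number as a block the contrast was 0.78 (95% interval -0.17 to 1.73). It was 0.69 within the lower title numbers (1 S and 2 congenic rats) and 0.87 within the higher (2 S and 1 congenic). These are too few rats to exclude a processing order marked by that number. Higher glucocorticoid exposure also stays open, since 10 of 17 target genes were positive (camera adjusted p = 0.275 over the 2 added lists). Time of collection is not in the labels, so it cannot be told apart from strain, and a strain effect on the clock remains an untested biological explanation.

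The shift of some gene lists could come from a difference that varies with signal, since the log2 difference rose with mean signal (Spearman's rho across genes 0.169, at most 0.139 in other splits). Among lists matched on signal, the oxidative phosphorylation median lay at the 40th percentile (39.97), as such a difference would give. The xenobiotic list lay at 91.05, ADAMTS at 5.76, the chromosome 1 neighbourhood at 97.46 and immune genes at 98.44, with matching done in 1 way only. None of these passed camera after quantile normalisation or cyclic loess, so such a difference stays open for them. The matrix median lay at percentile 0.13 and the loop of Henle median at 0.18, and both lists passed camera after quantile normalisation and cyclic loess, which argues against it for these lists. For proximal tubule markers it stays open, because the percentile was 99.3 with matching windows moved inward at the brightest genes and 88.9 with ranks clipped there. More cortex in the congenic pieces also stays open (camera adjusted p = 0.512 for collecting duct and medulla genes), as does a strain effect, which was not tested.

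The 87 probe sets with lower signals had a median log2 difference of -0.75, while 55 other tested probe sets of their genes had -0.090 and 65.5% of these were negative. A change in a part of the transcript that 1 probe set reads may underlie this, but the 36 higher probe sets had a median of 0.67 and the others of their genes 0.04, so that the choice of extreme probe sets stays open as the cause. The genes of the lower probe sets spanned a median of 40.5 kb in GRCr8, against 24.2 kb for all tested genes (1-sided permutation test for longer genes, p = 0.0034). Those of the higher ones spanned 17.1 kb (same permutation test, p = 0.883), and this test cannot detect a shorter span. Over all tested genes, however, the relation of log2 difference to span was weak (Spearman's rho -0.065) and reached a size of 0.108 in another split. A difference in RNA integrity stays open: 0 of the 3 control genes had 3' to 5' ratios apart between strains, which 3 arrays per group can neither establish nor exclude. Unnamed probe sets made up 28.7% of the 87 (Fisher's exact test, p = 0.0441), 19.4% of the 36 higher ones (p = 1) and 19.97% of those tested.

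As a hypothesis, a growth hormone pulse may have raised Cish through STAT5. Of 9 further genes of the STAT5 and growth hormone list, 8 were positive. The list includes Stat5a and the receptor gene Ghr, which are parts of the pathway, and Ccnd1 alone reached unadjusted p below 0.05. Camera gave the list adjusted p = 0.0362 over the 2 added lists, and adjusted p = 0.199 with an estimated correlation. Over 10 alternatives the adjusted p at the preset correlation was 0.0149 to 0.148, and 6 of them stayed below 0.05. It was 0.133 with the title number as a block, 0.146 without S replicate 2, 0.0876 without S replicate 3 and 0.148 without congenic replicate 1. A donor segment outside the Adamts16 region was also tested, and a window of 20 neighbouring genes on chromosome 20 held 6 at unadjusted p below 0.01 (Bcr, Zwint, Slc16a9, Ccdc6, Ank3 and Arid5b, permutation p = 0.0451). In 0 of the 10 alternatives did the highest window pass, with p from 0.124 to 1, so this stays open.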
